A study of Caenorhabditis elegans with 14 samples.

How the data were processed

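The values are raw counts of reads per gene, as deposited by the authors with 1 file per library, which the submitters' processing notes credit to STAR 2.7.10. DESeq2 is also named in those notes, without its role. The genome build and the annotation behind the counts were not given in the sources used here. Per the labels, eggs were isolated by bleaching, larvae hatched overnight without food and then grew on plates to the L4 stage. Total RNA was extracted with TRIzol, depleted of ribosomal RNA and sequenced as paired reads of 100 bases on a DNBSEQ instrument. No count was changed, imputed or left out before the tests, and no library was dropped.

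Each file held 46778 genes with a column of counts that ignores strand and a column for each strand. Of the gene IDs 46603 were found in the WBcel235 annotation of Ensembl, which supplied positions and exon lengths, and 43818 had a symbol. Counts in genes ran from 20571841 to 23396181 per library. Unmapped reads made up 0.577% to 2.96%, with the 2 highest shares (2.82% and 2.96%) in the pan-neuronal strain on K12 and at most 2.01% elsewhere. Reads mapped to several places made up 2.64% to 4.47%, reads outside genes 0.175% to 0.621% and reads in overlapping genes 1.41% to 1.91%. Genes of ribosomal RNA took 0.045% to 3.05% of counts.

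Groups, comparisons, tests, gene lists, the rule for naming genes and most alternatives were set before the data were examined. One choice was changed afterwards. The strand-specific column had been chosen because the labels name a strand-specific service. Since both pan-neuronal libraries on K12 hold reads of either strand in nearly equal shares, that column would have counted 50.9% and 51.4% of their gene reads, so the unstranded column was used in all 14 libraries. This was settled from the strand shares, before the calls of the 2 columns were compared, and the strand-specific column was kept as an alternative. In unstranded counts a gene that overlaps a neighbour on the opposite strand is uncertain. Reads that fit several near copies are not counted in genes, so members of families with near copies (major sperm proteins, vitellogenins, small heat shock genes, histones, ribosomal RNA, collagens and nematode-specific peptide families) are uncertain as single genes.

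Counts were scaled by TMM factors of 0.724 to 1.18 and filtered with filterByExpr by group, which left 16606 genes. All 14 libraries went into a joint edgeR quasi-likelihood fit with a mean per group and robust estimation (glmQLFit, glmQLFTest). This fit has 7 residual degrees of freedom, against 2 in a fit of a pair of groups, and a common biological coefficient of variation of 0.262. Benjamini-Hochberg adjusted p values under 0.05 were called, over all tested genes of a comparison and without a limit on the fold change. All tests were two-sided. The labels do not say that replicates came from separate cultures, so p values measure the spread between these samples. Both libraries of K12 with PA differed beyond counting noise (chi-square per degree of freedom 2.27 over genes with at least 20 reads in the pair) and were kept as 2 samples. Intervals and bounds from counts cover counting error only.

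Of 49 gene lists, 48 had at least 3 tested members. They were tested with camera on voom values with a preset correlation of 0.01 between genes, adjusted over the lists of each comparison. Camera called 233 lists over the 10 comparisons, of which 0 held with an estimated correlation and 185 were also called by fry. Neither fry nor a member count compares a list with other genes. A group without reads was compared through a lower bound, set at 3 reads over the group, and a group with 1 to 3 reads through the ratio with its exact 95% counting interval. With members without reads moved to their bounds, the 432 list medians differed by at most 0.227, and 9 of them by over 0.1.

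Genes were named by a rule in 4 parts. The first part took dat-1 and aex-3 in comparisons of strains. A second part took the genes of propionate breakdown, the methionine cycle and its regulators in comparisons of diet or supplement. The third part took the 8 largest fold changes each way (4 for the interaction) among called genes with an average log2 CPM of at least 1 and no overlap between the groups. The fourth part took up to 4 members with the smallest p of each list that camera called or of which at least 0.25 passed. The text prints a selection of these genes. The group levels of oma-1, mlt-11 and vit-2, and the members of the 18 genes that separate the control strain from all α-synuclein groups, were chosen after their values were seen.

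Overlaps between comparisons were set against the product of the list sizes and against 20 simulations of unchanged groups that share the same libraries. In simulated counts for the dopaminergic strain against the control, edgeR recovered 18 of 100 genes changed 2-fold and 76 of 100 changed 4-fold, with 6 false calls. For B12 on the depleted diet it recovered 14 and 73, with 9 false calls. DESeq2 recovered 37 and 89 (27 false calls) and 38 and 90 (36 false calls). Camera found the changed list (adjusted p = 1.4e-65) and called 0 of 48 unchanged lists. With no gene changed, edgeR called 0 genes for K12 with PA against the control, and a correlation made at 0.5 was recovered as 0.495. With few changed genes simulated, 2-fold changes were often missed, and a gene not called may have changed.

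Alternatives were RLE size factors, no filter on low counts, a DESeq2 Wald test, only the compared groups in the fit, a replicate block, strand-specific counts, a limit of 1 on the absolute log2 fold change, and leaving out each library in turn. A further 3 were chosen after seeing the data, namely fits without the pan-neuronal libraries on K12, counts without ribosomal RNA genes, and removal of the exon length trend of each library (12412 genes, 99.6% with a length). No sequencing date or batch is given in the labels. The records of the 3 groups on K12 without PA were numbered apart from those of the other 4 groups, so for comparisons across that divide a batch cannot be told apart from the groups. Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.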

Results

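RNA of whole Caenorhabditis elegans harvested at the L4 larval stage was sequenced in 7 groups of 2 libraries each. A control strain carried GFP in its dopamine neurons. The dopaminergic strain expressed a mutant human α-synuclein, a form linked to familial Parkinson's disease, from the promoter of the dopamine transporter gene dat-1. The pan-neuronal strain expressed the same protein from the aex-3 promoter, which is active throughout the nervous system. These 3 strains were grown on Escherichia coli K12. The pan-neuronal strain was also grown on K12 with propionic acid (PA), on K12 lacking the cobS and cobA genes of vitamin B12 handling (the depleted diet), and on the depleted diet with either 10 mM PA or 64 nM vitamin B12. The dose of PA given on K12 was not in the labels. Each library held between 20571841 and 23396181 reads counted in genes, and 13638 to 15473 genes had at least 10 reads. Values below are log2 fold changes ± SE from the joint edgeR quasi-likelihood fit with Benjamini-Hochberg adjusted p, or counts scaled to library size (CPM) ± SD with n = 2 per group. For every gene named as having risen or fallen in a comparison of a pair of groups, 2 of 2 libraries of 1 group lay above 2 of 2 of the other.

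On a principal component plot of all 16606 tested genes, the libraries of each group lay together, with 43.4% of the variance on the PC1 axis and 24.4% on the PC2 axis. Among the transcripts that differed between the groups were those of the maturing germ line and of the molt. The oocyte gene oma-1 measured 14 ± 5.24 CPM in the control strain, 65.5 ± 39.2 in the dopaminergic strain and 171 ± 42.7 in the pan-neuronal strain on K12. In the latter strain it measured 1.15 ± 0.137 CPM on K12 with PA, 84.8 ± 46.9 on the depleted diet, 60.2 ± 14.9 with added PA and 442 ± 28.9 with added B12. The molting gene mlt-11 ran from 15.2 ± 12.9 CPM on the depleted diet with PA to 1512 ± 129 on K12 with PA. The yolk protein gene vit-2 measured 124 ± 12.1 CPM on K12 with PA, the lowest of the 7 groups, and 23160.0 ± 1880.0 with added B12, the highest.

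**Figure D1:**
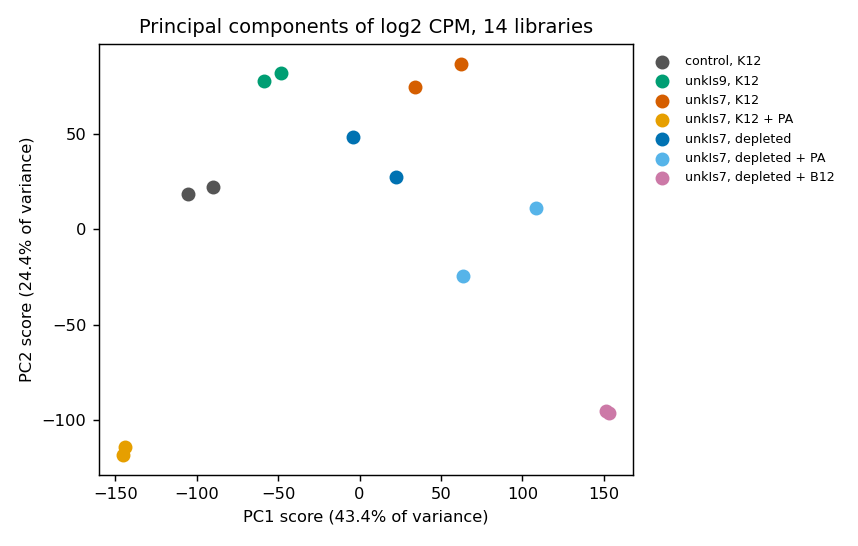
Principal component scores of the 14 libraries, PC1 (43.4% of variance) against PC2 (24.4%), with a point per library coloured by group. The pan-neuronal libraries on K12 with PA lie at −143.97 and −145 on PC1, and those on the depleted diet with B12 at 151.33 and 152.95.

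**Figure D2:**
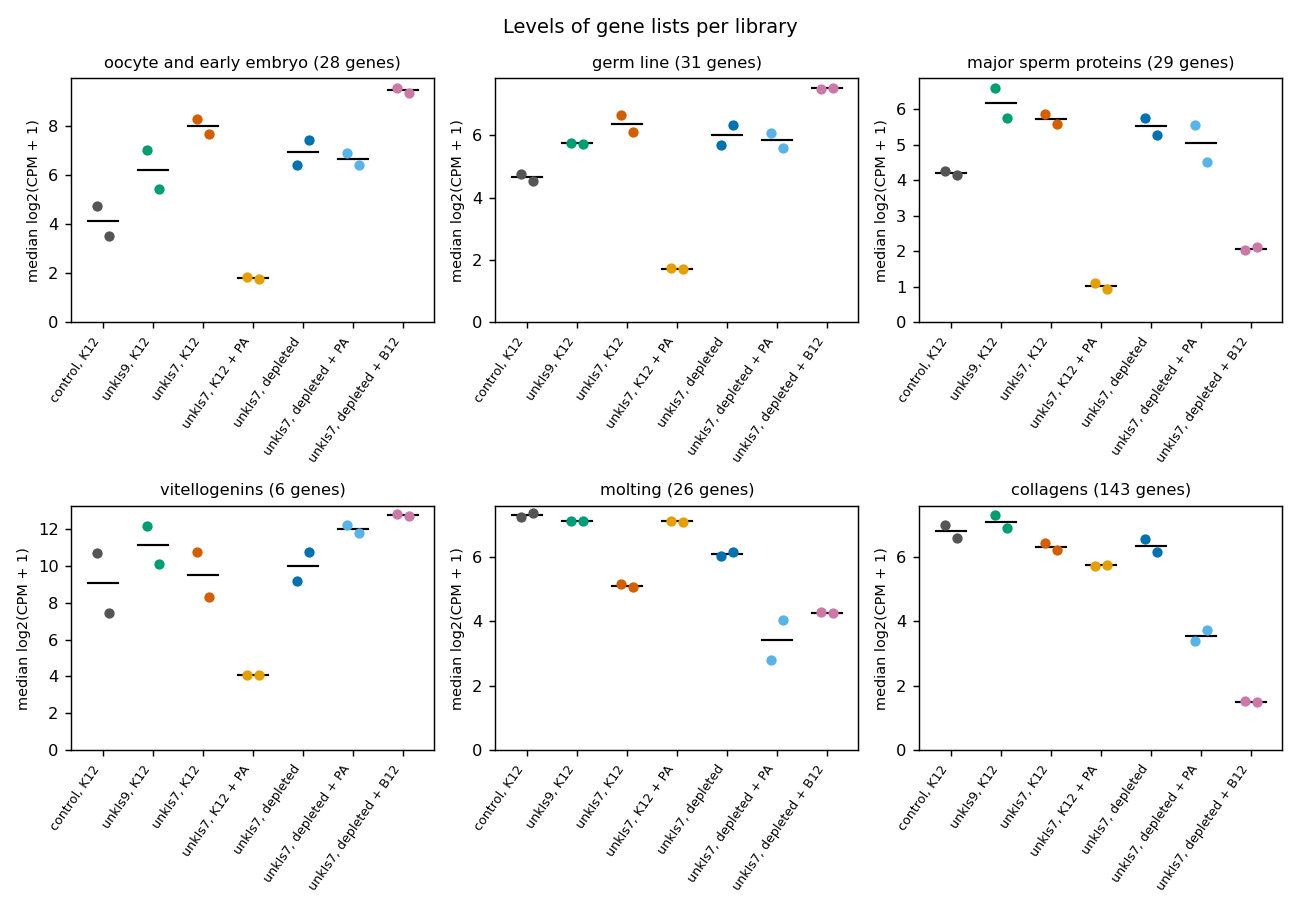
Median log2(CPM + 1) of the tested members of 6 gene lists in each library, with a point per library and a line at the mean of each group of 2. The 28 oocyte and early embryo genes, 31 germ line genes, 29 major sperm protein genes and 6 vitellogenins are lowest on K12 with PA, the 26 molting genes are highest in the control strain, and the 143 collagens are lowest on the depleted diet with B12.

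A strand-specific library kit was named in the labels, but the 2 pan-neuronal libraries on K12 held no strand information. In these 50.9% and 51.4% of gene reads lay on the annotated strand, against 93.8% to 98.2% in the other 12 libraries. All comparisons therefore use unstranded counts, in which a gene and an overlapping antisense partner cannot be separated. Each of the 5 comparisons that involve this group, which include its comparisons with both K12 strains, with PA on K12 and with the depleted diet, also compares a pair of library preparations. PA, B12 and PA against B12 on the depleted diet, and the dopaminergic strain and K12 with PA against the control, match by strand. K12 with PA against the control may cross batches.

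**Figure D3:**
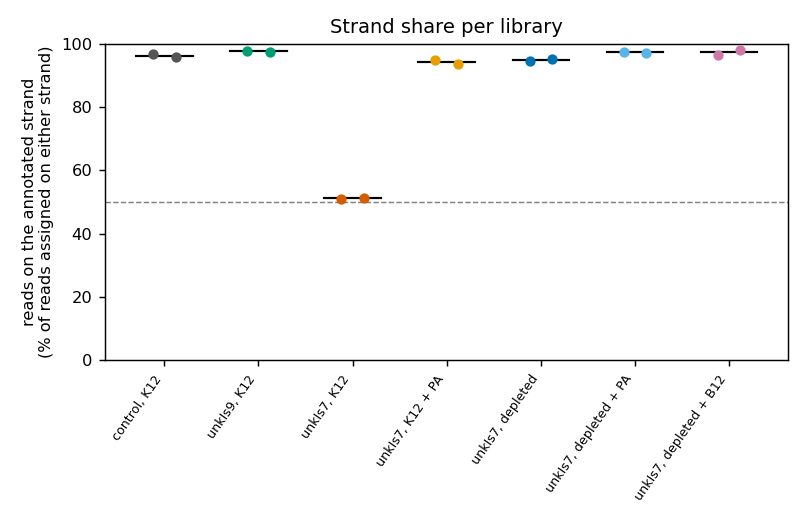
Percent of gene reads on the annotated strand in each library, with a point per library, a bar at the mean of each group of 2 and a dashed line at 50. The pan-neuronal strain on K12 lies at 50.9% and 51.4%, and the other 12 libraries at 93.8% to 98.2%.

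**Figure D4:**
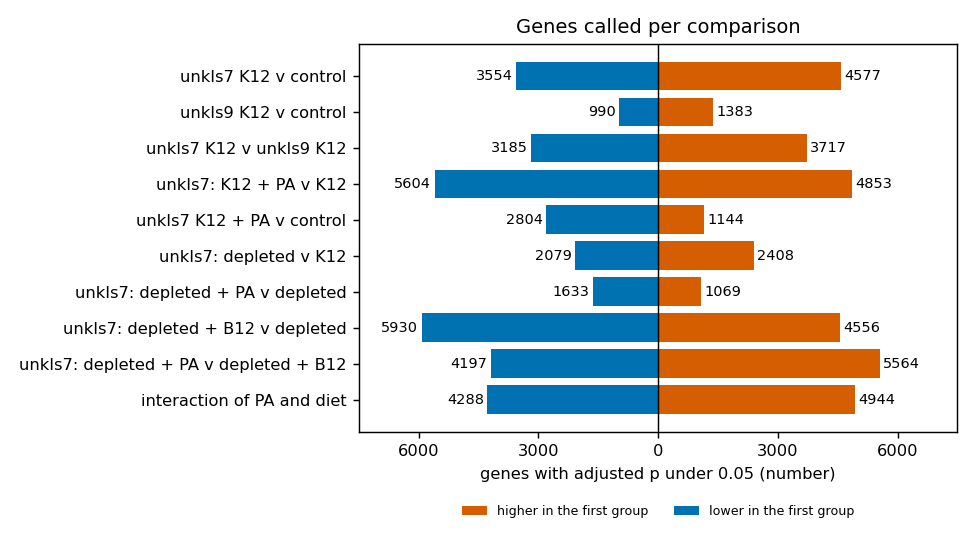
Numbers of genes higher (orange, to the right) and lower (blue, to the left) in the group named first in each of the 10 comparisons, of 16606 tested, at the false discovery rate threshold of 0.05. They range from 2373 for the dopaminergic strain against the control to 10486 for B12 on the depleted diet.

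The pan-neuronal strain was set against the control strain on K12. Besides α-synuclein, harvest stage may differ and was not tested. Most members of the oocyte, germ line and major sperm protein lists were higher in the pan-neuronal strain. Most members of the propionate shunt, fatty acid oxidation, cytochrome P450, intestinal and molting lists were lower. Of 16606 tested genes, 4577 were higher and 3554 lower (edgeR, 56.3% higher). Without replicate 1 or 2 of the control strain 2664 and 2516 were higher and 3043 and 3048 lower (46.7% and 45.2% higher), so the balance of directions rested on single libraries. Of the oocyte and early embryo genes, 28 of 28 (28 adjusted over the list alone) rose, with a median log2 fold change of 3.89. The oocyte and early embryo list gave adjusted p = 0.435 with an estimated correlation. The RNA-binding protein genes mex-5 (4.24 ± 0.51, adjusted p = 5.36e-05), spn-4 (4.67 ± 0.58) and mex-3 (3.49 ± 0.40) rose. Of the germ line list 29 of 31 (29 adjusted over the list alone) rose, among them daz-1 (3.13 ± 0.32; median 1.49, adjusted p = 0.435 with an estimated correlation). Major sperm protein genes, whose near copies share reads, rose in 22 of 29 (25 adjusted over the list alone), with msp-10 at 3.48 ± 0.41. The major sperm protein list gave adjusted p = 0.533 with an estimated correlation.

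The propionate shunt, which breaks down propionate without vitamin B12, fell in 4 of its 5 genes (4 adjusted over the list alone). The propionate shunt list gave adjusted p = 0.244 with an estimated correlation. The propionyl-CoA dehydrogenase acdh-1 fell from 2536 ± 662 to 202 ± 73.5 CPM (−3.65 ± 0.35, adjusted p = 1.03e-05), and ech-6 (−3.76 ± 0.25), hphd-1 (−4.73 ± 0.35) and hach-1 (−2.83 ± 0.29) fell with it. Fatty acid oxidation genes fell in 23 of 33 (23 adjusted over the list alone) cases, including the peroxisomal acyl-CoA oxidase acox-1.4 (−5.53 ± 0.37) and the carnitine palmitoyltransferase cpt-4 (−6.09 ± 0.47). The fatty acid oxidation list gave adjusted p = 0.175 with an estimated correlation. Of cytochrome P450 genes, 5 higher and 41 lower of 70 tested (6 and 42 adjusted over the list alone) changed, with cyp-35A5 at −5.58 ± 0.45. The cytochrome P450 list gave adjusted p = 0.168 with an estimated correlation. Intestinal genes fell in 15 of 20 (16 adjusted over the list alone) cases, including the metallothionein mtl-2 (−4.36 ± 0.36) and the microvillar actin act-5 (−3.62 ± 0.39). The intestinal list gave adjusted p = 0.0623 with an estimated correlation. Molting genes fell in 19 of 26 (21 adjusted over the list alone) cases and rose in 3, with the cuticle-shedding protease nas-37 at −2.49 ± 0.20. The molting list gave adjusted p = 0.345 with an estimated correlation. Nuclear-encoded respiratory chain genes fell in 22 of 33 (23 adjusted over the list alone) cases (nuo-5, −1.5 ± 0.19). The nuclear-encoded respiratory chain list gave adjusted p = 0.482 with an estimated correlation. Cytosolic heat shock genes rose in 13 of 20 (13 adjusted over the list alone) cases, among them hsp-12.6 (5.96 ± 0.66) and the transcription factor hsf-1 (1.25 ± 0.20). The cytosolic heat shock list gave adjusted p = 0.654 with an estimated correlation, and its camera call was lost without replicate 1 of the pan-neuronal strain (adjusted p = 0.172, range 2.44e-06 to 0.172 over the alternatives). The median log2(CPM + 1) of this list was 8.40 and 5.80 in the 2 pan-neuronal libraries and 5.64 and 5.66 in the control strain, so the increase rested mainly on 1 library. Of genes marking dopamine neurons 6 of 12 (6 adjusted over the list alone) fell, including the amine synthesis enzymes bas-1 (−3.26 ± 0.34) and cat-4 (−1.71 ± 0.30). The dopamine neuron list gave adjusted p = 0.435 with an estimated correlation. Pan-neuronal genes gave 4 higher and 10 lower of 29 tested (4 and 12 adjusted over the list alone) (adjusted p = 0.636 with an estimated correlation), ionotropic glutamate receptors 1 higher and 5 lower of 17 tested (1 and 5 adjusted over the list alone) and glia 0 higher and 5 lower of 10 tested (0 and 5 adjusted over the list alone). The ionotropic glutamate receptor and glia lists gave adjusted p = 0.654 with an estimated correlation and adjusted p = 0.482 with an estimated correlation. Camera calls of all 3 were lost without replicate 1 of the pan-neuronal strain (adjusted p = 0.064, 0.216 and 0.067 in this order, ranges 0.0113 to 0.064, 0.00634 to 0.216 and 0.00275 to 0.067 over the alternatives), and that of the receptors also without replicate 2 of the control strain (0.0504).

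Among the largest changes, F56A4.3 was at least 43.2-fold, C45H4.14 at least 25.7-fold and K10C2.14 at least 25.7-fold higher, with no reads in the control strain. The lysozyme gene ilys-3 rose to 48.7 ± 28.5 CPM (7.84 ± 0.59) and the collagen gene col-95 by 7.38 ± 0.82. The arginine kinase gene argk-1 fell from 409.6 ± 137 to 0.178 ± 0.0763 CPM (−11.14 ± 1.0, adjusted p = 1.4e-05). The lectin gene clec-258 (−8.58 ± 0.79), D1014.6 (−8.01 ± 0.72) and cyp-35B2 (−7.78 ± 0.67) also fell, and the lipid-binding protein gene lbp-8 was at least 79.4-fold lower. The catalase gene ctl-1 (chromosome II, 14303568 to 14306260, WBcel235) fell from 35.9 ± 5.59 CPM to a ratio of 0.000614 (exact interval 1.55e-05 to 0.00342). Of the genes whose promoters drive the transgenes, dat-1 did not pass the test (0.46 ± 0.46, adjusted p = 0.422). The aex-3 gene fell (−0.90 ± 0.34, adjusted p = 0.0433), a call that was lost in several alternatives (adjusted p = 0.159 with only the compared groups in the fit, 0.081 without replicate 1 of the control, 0.0791 without replicate 2 of the control, 0.139 without replicate 1 of the pan-neuronal strain on K12 and 0.118 under exon length trend removed per library, range 0.000121 to 0.159 over the alternatives). The library preparation changed with the strain in this comparison.

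The dopaminergic strain was set against the control strain, with the same limit on harvest stage. Here 1383 genes were higher and 990 lower of 16606 tested (edgeR). Most germ line and sperm list members were higher, and some detoxification and intracellular pathogen response members lower. F56A4.3 (chromosome V, 2453414 to 2456147) had no reads in the control and 30.1 ± 3.23 CPM in the dopaminergic strain, at least 432-fold higher, and C35E7.2 rose by 5.31 ± 0.79, adjusted p = 0.00373. The ctl-1 gene was at least 449.9-fold and F33E2.5 at least 44.3-fold lower. D1014.6 (−6.07 ± 0.64, adjusted p = 0.000557), its neighbour D1014.7 (−5.43 ± 0.57), the glycosyltransferase gene gly-1 (−4.75 ± 0.64), Y71G12B.18 (−4.34 ± 0.65) and BE0003N10.6 (−3.71 ± 0.50) also fell. Cytochrome P450 genes fell in 21 of 70 (33 adjusted over the list alone) and rose in 3 cases, with cyp-33B1 at −3.47 ± 0.52 and cyp-25A2 at −2.35 ± 0.35. The cytochrome P450 list gave adjusted p = 0.242 with an estimated correlation. UDP-glucuronosyltransferases fell in 14 of 63 (20 adjusted over the list alone) cases, with ugt-39 at −2.03 ± 0.31 and ugt-17 at −2.49 ± 0.43. The UDP-glucuronosyltransferase list gave adjusted p = 0.369 with an estimated correlation. Of intracellular pathogen response genes 6 of 18 (7 adjusted over the list alone) fell, including pals-32 (−3.25 ± 0.46) and the ubiquitin ligase components skr-3 (−1.73 ± 0.25) and cul-6 (−2.18 ± 0.36). The intracellular pathogen response list gave adjusted p = 0.372 with an estimated correlation. Nuclear hormone receptor genes fell in 31 of 197 (32 adjusted over the list alone) cases, among them nhr-8 (−1.13 ± 0.19) and nhr-102 (−1.77 ± 0.29). The nuclear hormone receptor list gave adjusted p = 0.432 with an estimated correlation. Of shunt genes 1 of 5 (1 adjusted over the list alone) fell, acdh-1 (−1.27 ± 0.32, adjusted p = 0.0221; adjusted p = 0.156 without replicate 2 of the control, 0.124 without replicate 1 of the dopaminergic strain and 0.0645 without replicate 2 of the dopaminergic strain, range 2.48e-05 to 0.156 over the alternatives). The propionate shunt list gave adjusted p = 0.509 with an estimated correlation, and lost its camera call in 4 alternatives (range 0.000653 to 0.394).

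Major sperm protein genes rose in 29 of 29 (29 adjusted over the list alone) (median 2.11, adjusted p = 0.372 with an estimated correlation), oocyte and early embryo genes in 26 of 28 (28 adjusted over the list alone) (adjusted p = 0.477 with an estimated correlation) and germ line genes in 22 of 31 (25 adjusted over the list alone). The germ line list gave adjusted p = 0.432 with an estimated correlation. Pharyngeal genes rose in 14 of 21 (17 adjusted over the list alone). The pharyngeal list gave adjusted p = 0.432 with an estimated correlation. The msp-142 gene rose by 2.02 ± 0.32, adjusted p = 0.00436 (adjusted p = 0.0547 without replicate 2 of the control, range 7.27e-08 to 0.0547 over the alternatives), mex-5 by 2.26 ± 0.46, adjusted p = 0.0113 (adjusted p = 0.117 without replicate 2 of the control and 0.138 without replicate 1 of the dopaminergic strain, range 4.67e-14 to 0.138 over the alternatives) and the pharyngeal myosin gene myo-1 by 2.24 ± 0.43, adjusted p = 0.00896 (adjusted p = 0.0757 without replicate 1 of the control, range 1.02e-11 to 0.0757 over the alternatives). The dat-1 gene rose from 1.99 ± 0.376 to 11.4 ± 3.48 CPM (2.52 ± 0.46, adjusted p = 0.00744; adjusted p = 0.0607 without replicate 1 of the control, 0.0562 without replicate 2 of the control and 0.0692 without replicate 1 of the dopaminergic strain, range 7.07e-07 to 0.0692 over the alternatives), and aex-3 did not pass (−0.34 ± 0.34, adjusted p = 0.523). The totals fell to 277 genes (116 higher and 161 lower) without replicate 1 of the dopaminergic strain. Without replicate 1 of the control strain 625 passed (308 and 317), against 325 (63 and 262) without its replicate 2. Replicate 1 of the dopaminergic strain held 3.05% of its reads in ribosomal RNA genes against at most 0.396% in the other 13 libraries.

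The calls of the 2 strain comparisons overlapped in 1647 genes, 93.6% of them in the same direction. A total of 1002 genes were higher in both, against 381.2 for independent lists of these sizes, and 539 lower in both, against 211.9. The log2 fold changes correlated across genes at r = 0.447, where simulated unchanged groups sharing the control gave 0.493, and their covariance was 0.808 against 0.129. The 2 control libraries were not divided, as each part would hold 1 library, so part of the excess may come from them, and genes are not independent replicates.

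The pan-neuronal strain was also set directly against the dopaminergic strain, with the same limit on harvest stage. It had 3717 higher and 3185 lower genes of 16606 tested (edgeR), and 2368 and 2694, or 2477 and 2835, without replicate 1 or 2 of the dopaminergic strain. Nuclear-encoded respiratory chain genes fell in 25 of 33 (25 adjusted over the list alone) cases, with cox-6C at −2.24 ± 0.25, adjusted p = 4.83e-05 and nuo-5 at −1.73 ± 0.19. The nuclear-encoded respiratory chain list gave adjusted p = 0.362 with an estimated correlation. Tricarboxylic acid and glyoxylate cycle genes fell in 20 of 27 (22 adjusted over the list alone) cases, with the aconitase gene aco-1 at −2.04 ± 0.21. The tricarboxylic acid cycle list gave adjusted p = 0.293 with an estimated correlation. Of fatty acid oxidation genes 22 of 33 (23 adjusted over the list alone) fell, including kat-1 (−2.23 ± 0.21) and acox-1.4 (−4.25 ± 0.35). The fatty acid oxidation list gave adjusted p = 0.215 with an estimated correlation. Shunt genes fell in 4 of 5 cases (4 adjusted over the list alone), with hphd-1 at −4.38 ± 0.35 and acdh-1 at −2.38 ± 0.33. The propionate shunt list gave adjusted p = 0.259 with an estimated correlation. Intracellular pathogen response genes rose in 10 of 18 (10 adjusted over the list alone) cases, including pals-14 (5.02 ± 0.65) and pals-32 (4.97 ± 0.46). The intracellular pathogen response list gave adjusted p = 0.37 with an estimated correlation.

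Oocyte and early embryo genes rose in 18 of 28 (23 adjusted over the list alone) cases (mei-2, 2.08 ± 0.42, adjusted p = 0.00205; adjusted p = 0.456 with an estimated correlation), while molting genes fell in 20 of 26 (20 adjusted over the list alone) (mlt-10, −3.57 ± 0.54; adjusted p = 0.188 with an estimated correlation) and collagens in 58 of 143 (60 adjusted over the list alone) (col-157, −2.08 ± 0.17). The collagen list gave adjusted p = 0.472 with an estimated correlation. Pharyngeal genes fell in 13 of 21 (13 adjusted over the list alone), with abu-14 at −4.96 ± 0.60. The pharyngeal list gave adjusted p = 0.424 with an estimated correlation. Large single changes were those of ilys-3 (7.98 ± 0.60, adjusted p = 1.22e-05), argk-1 (−10.10 ± 0.97, adjusted p = 4.13e-05), the lipase-related lips-6 (−8.13 ± 0.88), pud-3 (−7.69 ± 1.26), F30H5.3 (−7.49 ± 0.63) and H17B01.2 (−7.39 ± 0.57), and F33E2.5 was at least 44.4-fold higher. The dat-1 gene was lower in the pan-neuronal strain (−2.05 ± 0.45, adjusted p = 0.00332). With only these 2 groups in the fit, which leaves 2 residual degrees of freedom, 3630 genes passed. Library preparation and strain changed together here.

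Whether propionate acts on the pan-neuronal strain on bacteria that keep cobS and cobA was addressed by adding PA on K12. This comparison gave 4853 higher and 5604 lower genes of 16606 (edgeR). Yolk, sperm, oocyte and germ line transcripts fell, and most members of the molting, intestinal, pan-neuronal and cytochrome P450 lists rose. All tested members of 4 lists fell: 6 of 6 (6 adjusted over the list alone) vitellogenins (adjusted p = 0.634 with an estimated correlation; camera adjusted p = 0.0521 without replicate 1 of the pan-neuronal strain on K12, range 0.0112 to 0.0599 over the alternatives), 29 of 29 (29 adjusted over the list alone) major sperm proteins (adjusted p = 0.493 with an estimated correlation), 28 of 28 (28 adjusted over the list alone) oocyte and early embryo genes (adjusted p = 0.521 with an estimated correlation) and 31 of 31 (31 adjusted over the list alone) germ line genes. The germ line list gave adjusted p = 0.489 with an estimated correlation. The vit-2 gene fell from 10050.0 ± 8030.0 to 124 ± 12.1 CPM (−6.33 ± 0.99, adjusted p = 0.00023), mex-5 by −7.58 ± 0.60, oma-1 by −7.20 ± 0.60, the Piwi gene prg-1 by −4.59 ± 0.22, the cohesin gene rec-8 by −5.80 ± 0.32 and msp-81 by −6.17 ± 0.34. Among the largest decreases were the embryonic small heat shock gene sip-1 (−9.37 ± 0.64, adjusted p = 5.03e-07) and ZK813.2 (−9.36 ± 1.22), and rgs-9, a regulator of G protein signalling, was at least 138-fold lower, as were F31F6.2 by at least 88.1-fold and M151.3 by at least 58.8-fold.

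Molting genes rose in 19 of 26 (19 adjusted over the list alone) cases, with nas-37 at 2.65 ± 0.20 and ptr-18 at 2.56 ± 0.28. The molting list gave adjusted p = 0.489 with an estimated correlation. Of ionotropic glutamate receptor genes 14 of 17 (15 adjusted over the list alone) rose, including glr-1 (3.22 ± 0.53, adjusted p = 0.000192) and nmr-1 (3.33 ± 0.64; adjusted p = 0.567 with an estimated correlation), and of dopamine neuron genes 9 of 12 (9 adjusted over the list alone), including bas-1 (2.29 ± 0.33) and cat-4 (1.92 ± 0.30). The dopamine neuron list gave adjusted p = 0.489 with an estimated correlation. Pan-neuronal genes rose in 20 of 29 (24 adjusted over the list alone) cases. The pan-neuronal list gave adjusted p = 0.521 with an estimated correlation. Intestinal genes rose in 13 of 20 (13 adjusted over the list alone) cases, with mtl-2 at 3.08 ± 0.34 and act-5 at 3.13 ± 0.38. The intestinal list gave adjusted p = 0.354 with an estimated correlation. Cytochrome P450 genes gave 45 higher and 6 lower of 70 tested (47 and 6 adjusted over the list alone), with cyp-33A1 at 2.92 ± 0.23 and cyp-31A2 at −5.59 ± 0.49. The cytochrome P450 list gave adjusted p = 0.489 with an estimated correlation. Large increases were those of argk-1 (9.01 ± 0.95, adjusted p = 1.4e-05), the G protein gene gpa-6 (7.03 ± 0.85), cyp-35B2 (6.39 ± 0.65), the dehydrogenase gene dhs-23 (6.36 ± 0.83) and clec-210 (6.21 ± 1.0), and lbp-8 was at least 63.2-fold higher.

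Shunt genes rose in 4 of 5 cases (4 higher and 1 lower adjusted over the list alone). The propionate shunt list gave adjusted p = 0.521 with an estimated correlation, and lost its camera call with only these 2 groups in the fit (adjusted p = 0.061, range 0.0187 to 0.061 over the alternatives). The acdh-1 gene rose from 202 ± 73.5 to 1221 ± 0.0987 CPM (2.60 ± 0.33, adjusted p = 2.63e-05), hphd-1 by 3.14 ± 0.33, ech-6 by 2.59 ± 0.24 and hach-1 by 1.5 ± 0.27. The B12-dependent mutase gene mmcm-1 did not pass (−0.19 ± 0.16, adjusted p = 0.317). In the methionine and S-adenosylmethionine cycle, 8 higher and 2 lower of 17 tested (8 and 2 adjusted over the list alone) changed. The methionine cycle list gave camera adjusted p = 0.0537, adjusted p = 0.575 with an estimated correlation. The transsulfuration genes cth-1 (3.94 ± 0.54, adjusted p = 7.37e-05) and cbs-1 (2.33 ± 0.28), the methionine synthase reductase mtrr-1 (1.98 ± 0.28) and the hydroxymethyltransferase mel-32 (1.70 ± 0.28) rose, and sams-5 (−5.17 ± 0.43) and cbs-2 (−4.06 ± 0.65) fell. The nuclear receptor genes nhr-114 (2.49 ± 0.29, adjusted p = 1.24e-05) and nhr-68 (1.3 ± 0.34), which regulate B12-dependent metabolism, rose. The comparison crosses library preparations and holds the 2 libraries on K12 with PA, which agreed more closely with each other (chi-square per degree of freedom 2.27) than the pairs of the other 6 groups (14.9 to 132.3).

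**Figure D5:**
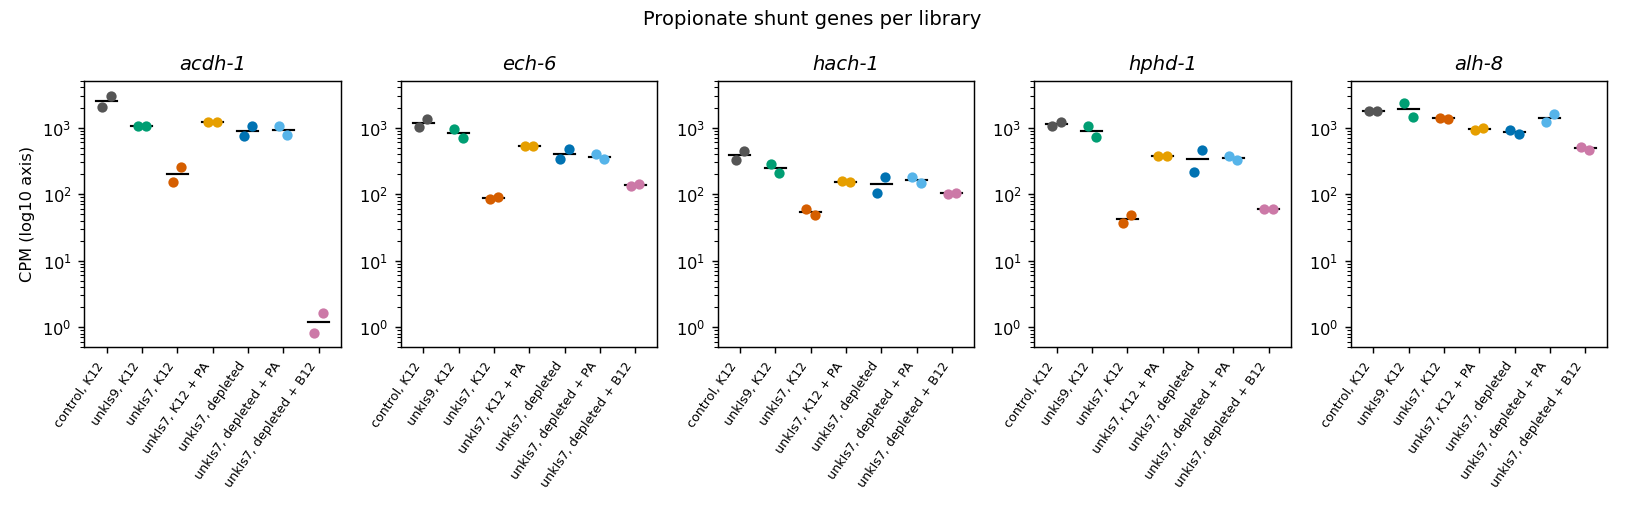
Level of the 5 propionate shunt genes in each library, in CPM on a log10 axis, with a point per library and a line at the mean of each group of 2. The acdh-1 mean runs from 1.21 CPM on the depleted diet with B12 to 2536 CPM in the control strain, and ech-6, hach-1 and hphd-1 are lowest in the pan-neuronal strain on K12 (87.6, 53.8 and 42.6 CPM).

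Changes of the pan-neuronal strain against the control and with PA on K12 share the pan-neuronal K12 libraries and ran in opposite directions. Of 6927 genes called in both, 0.953% went the same way. Of these, 3944 were higher in the pan-neuronal strain and lower with PA (1545 for independent lists) and 2917 the reverse (1039). The log2 fold changes correlated at r = −0.761 (simulated unchanged groups −0.503), with a covariance of −3.21 against −0.127. These 2 libraries, not divided, lack strand information, and the simulations hold no preparation shift, so PA and preparation cannot be told apart.

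K12 with PA in the pan-neuronal strain was also set against the control strain. It differed in 1144 higher and 2804 lower genes of 16606 (edgeR), free of the strand difference but not of a possible batch. Without any 1 library 239 to 255 genes were higher and 1890 to 2418 lower, and with only these 2 groups in the fit 4641 and 4685 (49.8% higher), so the number of higher genes was not stable. Sperm, germ line and yolk transcripts were lower than in the control strain. Major sperm proteins fell in 29 of 29 (29 adjusted over the list alone), with msp-81 at −4.21 ± 0.32, adjusted p = 9.53e-06. The major sperm protein list gave adjusted p = 0.438 with an estimated correlation. Germ line genes fell in 27 of 31 (27 adjusted over the list alone), among them prg-1 (−3.54 ± 0.21) and the P granule genes glh-1 (−3.57 ± 0.27) and pgl-1 (−3.98 ± 0.31). The germ line list gave adjusted p = 0.438 with an estimated correlation. Oocyte and early embryo genes fell in 23 of 28 (24 adjusted over the list alone), with mex-5 at −3.33 ± 0.50 and oma-1 at −3.60 ± 0.54. The oocyte and early embryo list gave adjusted p = 0.594 with an estimated correlation. Vitellogenins fell in 6 of 6 (6 adjusted over the list alone) (adjusted p = 0.509 with an estimated correlation), with vit-2 at −5.35 ± 0.94, adjusted p = 0.00173, which was lost with 1 alternative (adjusted p = 0.0711 with only the compared groups in the fit, range 9.48e-79 to 0.0711 over the alternatives). Of FOXO target and longevity genes 11 of 22 (12 adjusted over the list alone) fell, including the glyoxylate cycle gene icl-1 (−3.43 ± 0.42). The FOXO target and longevity list gave adjusted p = 0.438 with an estimated correlation, and lost its camera call with only these 2 groups in the fit (adjusted p = 0.0628, range 0.0109 to 0.0628 over the alternatives).

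All 5 shunt genes were lower on K12 with PA than in the control strain (5 adjusted over the list alone; adjusted p = 0.438 with an estimated correlation), with hphd-1 at −1.59 ± 0.31, adjusted p = 0.00215, ech-6 at −1.17 ± 0.23 and hach-1 at −1.33 ± 0.27. The calls of acdh-1 (−1.05 ± 0.32, adjusted p = 0.0276; adjusted p = 0.109 without replicate 1 of K12 with PA, 0.11 without replicate 2 of K12 with PA and 0.157 without replicate 2 of the control, range 0.000279 to 0.157 over the alternatives) and alh-8 (−0.92 ± 0.24, adjusted p = 0.0128; adjusted p = 0.0848 without replicate 1 of K12 with PA and 0.0593 without replicate 2 of K12 with PA, range 7.2e-05 to 0.0848 over the alternatives) depended on single libraries. The sams-5 (−4.02 ± 0.42) and cbs-2 (−3.77 ± 0.65) genes also fell. Of nuclear hormone receptor genes 26 higher and 7 lower of 197 tested (21 and 6 adjusted over the list alone) changed (adjusted p = 0.537 with an estimated correlation), and nhr-155 was at least 32.6-fold higher. F56A4.3 was at least 967-fold higher, C35E7.2 rose by 6.80 ± 0.79, adjusted p = 6.11e-05, R11D1.3 by 5.37 ± 0.91 and Y71F9AL.7 by 5.27 ± 0.96, and the ratio of ctl-1 was 0.000587 (exact interval 1.49e-05 to 0.00328). The dat-1 gene measured 15.1 ± 1.48 CPM against 1.99 ± 0.376 (2.92 ± 0.47, adjusted p = 0.000572; adjusted p = 0.0502 under strand-specific counts, range 2.04e-09 to 0.0502 over the alternatives). Leaving out replicate 1 or 2 on K12 with PA, or replicate 1 of the control strain, left 2197, 2131 and 2488.

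The effect of the bacterial diet on the pan-neuronal strain was addressed by comparing the depleted diet with K12. It gave 2408 higher and 2079 lower genes of 16606 (edgeR, 53.7% higher), and 1973 higher and 2638 lower (42.8%) with RLE size factors, which moved the median of all tested genes from 0.13 to −0.01. Without replicate 1 on K12, 1456 were higher and 1633 lower, and without replicate 1 on the depleted diet 1260 and 938. Members of the shunt, fatty acid oxidation and detoxification lists were among the higher genes, and germ line members among the lower. The acdh-1 gene rose from 202 ± 73.5 to 891 ± 220.0 CPM (2.14 ± 0.33, adjusted p = 0.000751), with hphd-1 at 3.0 ± 0.33, ech-6 at 2.21 ± 0.24 and hach-1 at 1.39 ± 0.27 (4 of 5 shunt genes higher and 1 lower, 4 and 1 adjusted over the list alone). The propionate shunt list gave adjusted p = 0.514 with an estimated correlation. Of the remaining B12-related genes, cth-1 (3.10 ± 0.52, adjusted p = 0.0017) and cbs-1 (1.86 ± 0.28) rose. Calls of nhr-114 (1.35 ± 0.28, adjusted p = 0.00411; adjusted p = 0.0512 with only the compared groups in the fit and 0.053 without replicate 1 of the pan-neuronal strain on K12, range 8.9e-06 to 0.053 over the alternatives) and mtrr-1 (1.12 ± 0.27, adjusted p = 0.00997; adjusted p = 0.0612 with only the compared groups in the fit, 0.0664 without replicate 2 of the depleted diet and 0.0654 without replicate 1 of the pan-neuronal strain on K12, range 0.000233 to 0.0664 over the alternatives) were lost in some alternatives.

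Fatty acid oxidation genes rose in 12 of 33 (12 adjusted over the list alone) cases, including acox-1.4 (2.93 ± 0.33, adjusted p = 0.000157) and cpt-4 (2.93 ± 0.41). The fatty acid oxidation list gave adjusted p = 0.514 with an estimated correlation. Cytochrome P450 genes gave 26 higher and 3 lower of 70 tested (28 and 3 adjusted over the list alone), with cyp-35A3 at 5.22 ± 0.49 (adjusted p = 0.514 with an estimated correlation), and UDP-glucuronosyltransferases 27 higher and 3 lower of 63 tested (36 and 4 adjusted over the list alone), with ugt-22 at 3.69 ± 0.38. The UDP-glucuronosyltransferase list gave adjusted p = 0.514 with an estimated correlation. Of bacterial infection response genes 18 higher and 6 lower of 37 tested (19 and 6 adjusted over the list alone) changed, with irg-5 at 4.49 ± 0.44. The bacterial infection response list gave adjusted p = 0.474 with an estimated correlation. Cytosolic heat shock genes fell in 14 of 20 (15 adjusted over the list alone) cases, among them hsp-12.6 (−4.14 ± 0.55, adjusted p = 0.000355) and the co-chaperone sti-1 (−2.02 ± 0.34). The cytosolic heat shock list gave adjusted p = 0.644 with an estimated correlation. Its median log2(CPM + 1) was 8.40 in replicate 1 on K12, but 5.80 in replicate 2 against 5.74 and 6.04 on the depleted diet, so the size of the decrease rested mainly on 1 library, although the camera call stayed without it. The small heat shock gene hsp-16.41 measured 4.05 ± 1.16 CPM against 414 ± 521 (−6.67 ± 1.04, adjusted p = 0.00131; adjusted p = 0.0792 with only the compared groups in the fit, range 1.54e-78 to 0.0792 over the alternatives). Autophagy genes fell in 9 of 23 (9 adjusted over the list alone), with lgg-2 at −2.40 ± 0.37 (adjusted p = 0.514 with an estimated correlation), and germ line genes in 12 of 31 (12 adjusted over the list alone), with daz-1 at −1.73 ± 0.30 and fog-1 at −1.92 ± 0.30. The germ line list gave adjusted p = 0.865 with an estimated correlation. Large single increases were pud-3 (7.42 ± 1.25, adjusted p = 0.00187), argk-1 (7.35 ± 0.93), nspe-1 (7.20 ± 0.83), lips-6 (6.25 ± 0.87) and dhs-23 (5.73 ± 0.83), and C50F7.5 fell by −4.88 ± 0.91. With only these 2 groups in the fit 1672 genes passed. Library preparation changed with the diet, and fold changes followed exon length across genes at rho = −0.149 (1914 higher and 2407 lower, 44.3% higher, once the length trend of each library was removed).

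Whether propionate acts when bacterial B12 is depleted was addressed by adding PA on that diet. This gave 1069 higher and 1633 lower genes of 16606 (edgeR, 39.6% higher), against 1438 and 1259 (53.3%) with RLE size factors, which moved the median of all tested genes from −0.12 to 0.04. Without replicate 1 of the depleted diet, 363 were higher and 806 lower. These were 452 and 1273 without its replicate 2, and 1769 and 1270 without replicate 2 of the depleted diet with PA. Many collagens and most molting genes fell with PA, and single lysosomal, lysozyme and insulin-like genes rose, while the shunt did not respond detectably. The acdh-1 gene measured 909 ± 184 CPM with PA and 891 ± 220.0 without (0.03 ± 0.31, adjusted p = 0.962), hphd-1 0.05 ± 0.30, hach-1 0.23 ± 0.27 and ech-6 −0.16 ± 0.23. The alh-8 gene stood at 0.71 ± 0.23, adjusted p = 0.0558 and passed in some alternatives (adjusted p = 0.0259 under RLE size factors, 0.0398 under no filter on low counts, 0.0485 under strand-specific counts, 0.047 without replicate 1 of the depleted diet with PA, 0.0265 under exon length trend removed per library and 0.00761 under DESeq2 Wald test, range 0.00761 to 0.244 over the alternatives). By edgeR 0 of 5 shunt genes passed, over all genes and adjusted over the list alone. Collagens fell in 66 of 143 (81 adjusted over the list alone), including col-157 (−3.84 ± 0.18, adjusted p = 4.21e-07) and col-145 (−4.08 ± 0.23). The collagen list gave adjusted p = 0.566 with an estimated correlation. Molting genes fell in 21 of 26 (21 adjusted over the list alone), including ptr-18 (−3.14 ± 0.29) and the period homologue lin-42 (−2.99 ± 0.40). The molting list gave adjusted p = 0.308 with an estimated correlation. Hypodermis and seam genes fell in 15 of 22 (17 adjusted over the list alone), with the cuticle genes bli-1 (−4.79 ± 0.41) and bli-6 (−3.80 ± 0.46) and the receptor gene nhr-23 (−1.34 ± 0.18). The hypodermis and seam list gave adjusted p = 0.566 with an estimated correlation.

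Lysosomal genes rose in 8 of 32 (9 adjusted over the list alone) cases, with the glucocerebrosidase gene gba-4 at 2.31 ± 0.29, adjusted p = 0.000274, the cathepsin B gene cpr-1 at 2.39 ± 0.30 and asp-6 at 1.44 ± 0.26. The lysosomal list gave adjusted p = 0.566 with an estimated correlation. Of bacterial infection response genes 10 higher and 6 lower of 37 tested (11 and 8 adjusted over the list alone) changed, with lys-7 at 2.95 ± 0.34, lys-8 at 1.48 ± 0.20 and irg-5 at −3.01 ± 0.41. The bacterial infection response list gave adjusted p = 0.343 with an estimated correlation, and its camera call was lost without replicate 2 of the depleted diet with PA (adjusted p = 0.0692, range 0.00683 to 0.0692 over the alternatives). FOXO target and longevity genes rose in 8 of 22 (9 adjusted over the list alone) cases, including hsp-12.6 (4.19 ± 0.55) and the metallothionein mtl-1 (3.58 ± 0.47). The FOXO target and longevity list gave adjusted p = 0.0908 with an estimated correlation. The insulin-like gene ins-19 had no reads on the depleted diet and 57.2 ± 75.6 CPM with PA, at least 1023-fold higher, with a wide spread (adjusted p = 0.00505; adjusted p = 0.414 with only the compared groups in the fit, range 1.47e-58 to 0.414 over the alternatives). C27A7.8 (5.71 ± 0.49, adjusted p = 2.14e-05), Y37H2A.13 (5.54 ± 0.70), nlp-56 (5.47 ± 0.62) and F17E9.2 (5.04 ± 0.51) were the next largest increases that held in every alternative, and F18F11.4 (−4.49 ± 0.51) and F27E5.3 (−4.56 ± 0.72) fell. Both vit-2 (1.97 ± 0.81, adjusted p = 0.124) and sams-1 (−1.34 ± 0.52, adjusted p = 0.106) missed the threshold and passed in some alternatives (ranges 3.18e-14 to 0.429 and 5.45e-06 to 0.306). The folate and methionine genes mthf-1 (−1.21 ± 0.21, adjusted p = 0.00228; adjusted p = 0.054 without replicate 2 of the depleted diet with PA, range 7.04e-05 to 0.054 over the alternatives) and metr-1 (−1.45 ± 0.28, adjusted p = 0.00429; adjusted p = 0.0702 without replicate 2 of the depleted diet with PA, range 8.11e-07 to 0.0702 over the alternatives) fell. With only these 2 groups in the fit 1473 genes passed. Fold changes followed exon length (rho = −0.36 across genes; 1127 higher and 1144 lower, 49.6% higher, with the length trend removed).

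Adding vitamin B12 on the depleted diet asks which transcripts respond to the vitamin. B12 gave 4556 higher and 5930 lower genes of 16606 (edgeR, 43.5% higher), against 5882 and 4565 (56.3%) with RLE size factors, under which the median of all tested genes moved from −0.35 to 0.06. Without replicate 1 of the depleted diet, 3008 were higher and 4347 lower. The acdh-1 gene fell from 891 ± 220.0 to 1.21 ± 0.574 CPM (−9.52 ± 0.46, adjusted p = 6.72e-08). The other shunt genes moved less, hphd-1 by −2.51 ± 0.32, adjusted p = 5.87e-05 and ech-6 by −1.57 ± 0.23, and hach-1 did not pass (−0.46 ± 0.27, adjusted p = 0.145; 0.0302 to 0.927 over the alternatives, passing without replicate 1 of the depleted diet). The alh-8 gene fell (−0.82 ± 0.24, adjusted p = 0.00907; adjusted p = 0.151 under RLE size factors, 0.0667 without replicate 1 of the depleted diet, 0.0706 without replicate 2 of the depleted diet with B12, 0.0797 under exon length trend removed per library and 0.174 under DESeq2 Wald test, range 0.00251 to 0.174 over the alternatives). Over the shunt list 4 of 5 (4 adjusted over the list alone) fell (adjusted p = 0.736 with an estimated correlation). The regulators nhr-68 (−1.80 ± 0.35, adjusted p = 0.000800) and nhr-114 (−1.59 ± 0.28) fell, as did sams-1 (−2.40 ± 0.54), sams-5 (−3.34 ± 0.39), cbs-2 (−3.0 ± 0.65), mthf-1 (−0.99 ± 0.21) and the phosphoethanolamine methyltransferases pmt-1 (−1.34 ± 0.27) and pmt-2 (−1.18 ± 0.28). The mutase gene mmcm-1 rose by 0.63 ± 0.16, adjusted p = 0.00536 (adjusted p = 0.0531 under no filter on low counts, range 6.32e-09 to 0.0531 over the alternatives).

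Outside B12 metabolism, values stand against the median of −0.35 for all tested genes. Of 143 collagens 5 rose, 19 did not pass and the rest fell (121 lower adjusted over the list alone), with col-157 at −7.32 ± 0.23, adjusted p = 2.04e-09, col-145 at −7.70 ± 0.28 and col-156 at −8.51 ± 0.49. The collagen list gave adjusted p = 0.736 with an estimated correlation. The collagens that rose included col-165 (7.68 ± 0.80), col-74 (7.51 ± 0.61) and col-121 (7.12 ± 0.66). The cuticle genes dpy-14 (8.88 ± 1.02, adjusted p = 5.82e-05) and dpy-17 (7.67 ± 0.61), outside this list, also rose, along with the protease gene hch-1 (7.73 ± 0.95) and pqn-73 (7.47 ± 0.63). Molting genes fell in 20 of 26 (20 adjusted over the list alone). The molting list gave adjusted p = 0.736 with an estimated correlation. Body wall muscle genes fell in 19 of 23 (20 adjusted over the list alone), with the troponin genes pat-10 (−2.65 ± 0.22) and mup-2 (−3.08 ± 0.27). The body wall muscle list gave adjusted p = 0.736 with an estimated correlation. Oocyte and early embryo genes rose in 28 of 28 (28 adjusted over the list alone) (mex-3, 2.35 ± 0.38; adjusted p = 0.736 with an estimated correlation) and germ line genes in 26 of 31 (26 adjusted over the list alone) (gld-3, 2.46 ± 0.33; adjusted p = 0.736 with an estimated correlation), whereas major sperm proteins fell in 29 of 29 (29 adjusted over the list alone) (msp-81, −3.93 ± 0.30). The major sperm protein list gave adjusted p = 0.736 with an estimated correlation. Proteasome genes rose in 27 of 33 (28 adjusted over the list alone) (rpn-1, 1.47 ± 0.26; adjusted p = 0.771 with an estimated correlation) and epidermal antimicrobial peptide genes fell in 14 of 19 (15 adjusted over the list alone) (nlp-30, −4.08 ± 0.41). The epidermal antimicrobial peptide list gave adjusted p = 0.771 with an estimated correlation. Ribosomal protein genes fell in 54 of 77 (58 adjusted over the list alone) (rpl-11.2, −2.45 ± 0.29). The ribosomal protein list gave adjusted p = 0.771 with an estimated correlation. Fold changes followed exon length (rho = 0.259; 5955 higher and 4406 lower, 57.5% higher, with the length trend removed).

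Calls with PA and with B12 on the depleted diet, which share the unsupplemented libraries, overlapped in 1880 genes, 83.6% of them in the same direction. There were 1250 genes lower with both, against 583.1 for independent lists, and 321 higher with both, against 293.3. RLE size factors gave 969 lower, against 346.1, and 682 higher, against 509.4. The correlation was r = 0.5003 against 0.4875 in simulated unchanged groups, and the covariance 1.15 against 0.121. Changes with the diet and with B12 overlapped in 3044 genes, of which 21.6% went the same way (covariance −0.464, simulated −0.12), while r = −0.199 was weaker than the −0.486 of simulated unchanged groups. Calls with PA on the 2 diets, which share no library, overlapped in 1999 genes, of which 29% went the same way (r = −0.102, simulated 0.00781; covariance −0.284).

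PA and B12 on the depleted diet were also compared directly. PA gave 5564 higher and 4197 lower genes than B12 (edgeR, 57% higher), against 4548 and 4874 (48.3%) with RLE size factors, under which the median of all tested genes moved from 0.39 to 0.14. Without replicate 1 of the depleted diet with B12, 3656 were higher and 3374 lower (52% higher). All 5 shunt genes were higher with PA (5 adjusted over the list alone; adjusted p = 0.644 with an estimated correlation), acdh-1 by 9.54 ± 0.46, adjusted p = 5.57e-07, hphd-1 by 2.56 ± 0.32, alh-8 by 1.53 ± 0.24 and ech-6 by 1.41 ± 0.23. The call of hach-1 was less secure (0.69 ± 0.27, adjusted p = 0.0412; adjusted p = 0.189 under RLE size factors, 0.0509 under replicate block, 0.181 without replicate 1 of the depleted diet with PA, 0.14 without replicate 1 of the depleted diet with B12, 0.133 without replicate 2 of the depleted diet with B12, 0.205 under exon length trend removed per library and 0.226 under DESeq2 Wald test, range 0.0116 to 0.226 over the alternatives). The regulators nhr-68 (1.67 ± 0.35) and nhr-114 (1.57 ± 0.28) and the methyltransferase gene pmt-1 (1.72 ± 0.28) were higher with PA. Collagens were higher with PA in 108 of 143 (111 adjusted over the list alone) (col-162, 4.21 ± 0.24; adjusted p = 0.644 with an estimated correlation), ribosomal protein genes in 55 of 77 (59 adjusted over the list alone) (rpl-25.1, 2.39 ± 0.27; adjusted p = 0.682 with an estimated correlation) and major sperm proteins in 28 of 29 (28 adjusted over the list alone) (msp-81, 3.13 ± 0.30). The major sperm protein list gave adjusted p = 0.644 with an estimated correlation. Epidermal antimicrobial peptide genes were higher in 17 of 19 (17 adjusted over the list alone) (nlp-26, 2.77 ± 0.42; adjusted p = 0.644 with an estimated correlation), and the immune genes ilys-3 (7.16 ± 0.57), clec-60 (5.20 ± 0.32) and lys-4 (5.15 ± 0.36) were too. Oocyte and early embryo genes were lower in 26 of 28 (26 adjusted over the list alone) (lin-41, −3.18 ± 0.36; adjusted p = 0.644 with an estimated correlation) and proteasome genes in 26 of 33 (26 adjusted over the list alone) (rpn-1, −2.13 ± 0.27). The proteasome list gave adjusted p = 0.682 with an estimated correlation.

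Of single genes, clec-70 was at least 88.1-fold and col-40 at least 52.5-fold higher with PA than with B12, T22F3.11 was higher by 7.79 ± 1.48, adjusted p = 0.00113, and col-121 (−7.67 ± 0.70, adjusted p = 1.18e-05), the cuticlin gene cut-3 (−7.58 ± 0.57), pqn-73 (−7.07 ± 0.62), col-165 (−6.92 ± 0.76), F30H5.3 (−7.35 ± 0.69) and R09E10.5 (−6.88 ± 0.68) were lower. Fold changes followed exon length at rho = −0.474 across genes. With the length trend of each library removed, 3806 genes were higher and 4730 lower (44.6% higher), so the balance of directions here is set by scaling.

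Whether the response to PA depends on the diet was tested as the interaction, the PA effect on the depleted diet minus that on K12. It passed in 9232 genes, 4944 positive and 4288 negative, of 16606 (edgeR). RLE size factors moved the median of all tested genes from 0.08 to 0.25. Of 5 shunt genes 1 had a positive interaction and 4 a negative one (1 and 4 adjusted over the list alone). Negative ones included acdh-1 at −2.57 ± 0.45, adjusted p = 0.000429, hphd-1 at −3.09 ± 0.44 and ech-6 at −2.75 ± 0.33, while alh-8 was at 1.27 ± 0.33. The propionate shunt list gave camera adjusted p = 0.075, adjusted p = 0.557 with an estimated correlation. Interactions were also negative for mtrr-1 (−3.09 ± 0.39), cth-1 (−3.55 ± 0.70), cbs-1 (−2.53 ± 0.38), sams-1 (−3.08 ± 0.74) and nhr-114 (−2.50 ± 0.39), and positive for sams-5 (3.9 ± 0.54). Yolk, oocyte, germ line and sperm genes, which fell with PA on K12, had positive interactions: 6 of 6 (6 adjusted over the list alone) vitellogenins (vit-2, 8.31 ± 1.26, adjusted p = 0.000265; adjusted p = 0.564 with an estimated correlation), 26 of 28 (26 adjusted over the list alone) oocyte and early embryo genes (mex-5, 7.09 ± 0.70; adjusted p = 0.495 with an estimated correlation), 30 of 31 (31 adjusted over the list alone) germ line genes (prg-1, 3.91 ± 0.28; adjusted p = 0.495 with an estimated correlation) and 28 of 29 (28 adjusted over the list alone) major sperm proteins (msp-81, 5.37 ± 0.41). The major sperm protein list gave adjusted p = 0.495 with an estimated correlation. Negative interactions prevailed for molting (20 of 26 (21 adjusted over the list alone); ptr-18, −5.71 ± 0.40; adjusted p = 0.419 with an estimated correlation) and pan-neuronal genes (19 of 29 (19 adjusted over the list alone); the kinesin gene unc-104, −3.33 ± 0.52). The pan-neuronal list gave adjusted p = 0.495 with an estimated correlation. The interaction uses the libraries without strand information in its K12 arm, and interaction values followed exon length at rho = −0.231.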

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

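Among the tests in this part, those on genes that set the pan-neuronal strain apart from every other group, on the germ line alone, on the shunt genes including acdh-1, and on linked loci were chosen only after the result was seen.

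The response to PA differed between the diets, tested as an interaction, in 9232 of 16606 genes. The largest positive interactions were those of ins-19 (log2 15.153, adjusted p = 0.036, then adjusted p = 0.11 under strand-specific counts, 0.0754 without replicate 1 of K12 with PA, 0.0863 without replicate 2 of K12 with PA, 0.0534 without replicate 1 of the depleted diet, 0.0506 without replicate 2 of the depleted diet, 0.242 without replicate 1 of the pan-neuronal strain on K12 and 0.207 without replicate 2 of the pan-neuronal strain on K12, range 9.06e-13 to 0.242 over the alternatives), nspc-13 (12.995), clec-222 (12.93) and ZK813.2 (12.724). The largest negative ones were those of argk-1 (−9.746), C27D9.2 (−9.184), clec-206 (−9.157) and lips-6 (−8.979). These fitted values depend on a prior count where a group has few reads.

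Outside the counts used for the comparisons, the strand that is nearly empty in the other libraries held 49.1048% and 48.5794% of gene reads in replicates 1 and 2 of the pan-neuronal strain on K12, against 1.83% to 6.23% in the other 12.

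Of the genes called between the pan-neuronal strain and the control strain on K12, 8.351% (679 of 8131) were called the same way against each of the other 5 groups, where library preparation without strand information as the main cause predicted over 80%. This group followed exon length at rho = −0.052 against the mean of the others. It was −0.128 against the control (dopaminergic strain −0.041), so transcript length bias of the unstranded libraries stays open. No group exceeded 35.82% (1414 of 3948, K12 with PA, which differs in strand information only from the pan-neuronal strain on K12). As the other groups also differ from each other, this test cannot exclude the preparation for any of the 8131 genes. The strain, which the design names, stays open and untested apart from the preparation, which both pan-neuronal libraries on K12 share.

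The pattern that germ-line, yolk and propionate shunt transcripts differ between the supplement groups may come from animals harvested at different developmental stages. The 26 molting genes had a median log2 fold change of −1.809 with B12 on the depleted diet. Further medians there were −4.297 (collagens), −1.503 (body wall muscle), −1.188 (intestine), −0.246 (pan-neuronal) and 1.486 (pharynx). In whole animals a larger germ line share would lower somatic lists alike, so these B12 values argue against a germ line change alone. With PA on K12 the molting median was 2.099 across library preparations but 0.399 against the control strain, leaving that change open for PA. The test for eggs in older animals, a summed level of 29 zygotic embryonic genes, gave 0.6103 for the lowest B12 library over the highest of the other 12, where stage predicted over 4, but excludes nothing, because these genes already measured 71 to 254.5 CPM without B12. The lowest acdh-1 level with PA on the depleted diet was 481.9 times the highest with B12, yet the B12 libraries lie beyond the oocyte levels of the others, so for acdh-1 stage and vitamin cannot be told apart. Of the other 4 shunt genes 3 fell to 1.5 times their B12 level or lower in a group without added B12 (animals harvested at different developmental stages, other 4 shunt genes), and the effect of the supplements, which the design names, stays open.

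In 18 genes that separate the control strain from every alpha-synuclein group (5 higher and 13 lower in those groups, each by an absolute log2 fold change of at least 2), 3 pairs lay within 100 kb, where random sets gave a median of 0 (0 to 2), a percentile of 99.4 over 10000 sets drawn from 8616 genes. These were D1014.6 with D1014.7 (chromosome V), C35E7.2 with C35E7.11 (chromosome I) and nhr-234 with nhr-235 (chromosome II). In the dopaminergic strain, without replicate 2 of the control, C35E7.11 and nhr-235 lost their calls but kept log2 fold changes of 4.877 and −2.594. Without both genes 1 pair is left, within the random range, but a fit with 1 control library cannot exclude them. Linked loci of a different genetic background therefore stay open, since neighbours can also share regulation or reads and the test was made on the genes in which the pattern was noticed. The α-synuclein transgenes and the background cannot be told apart, because no group here separates them.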

How the results depend on the processing

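The tests with the exon length trend removed, without ribosomal RNA genes and without the pan-neuronal libraries on K12 were chosen only after the data were seen. Each of the 10 totals stayed within 1.5 times its value under RLE size factors, DESeq2, no filter on low counts, strand-specific counts, a limit on the fold change, the replicate block, and each of the 3 added settings where they applied. In all, 126 alternative totals stayed within that limit and 13 moved. DESeq2 called 8321, 3351, 7122, 10422, 4366, 5120, 3347, 10493, 9480 and 9340 genes for the 10 comparisons in the order of the text, and strand-specific counts 8399, 2457, 7211, 10762, 4092, 5212, 2788, 10691, 9838 and 9285.

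With only the compared groups in the fit, totals were 3630 for the pan-neuronal against the dopaminergic strain, 9326 for K12 with PA against the control strain, 1672 for the depleted diet against K12 and 1473 for PA on the depleted diet. This setting has 2 residual degrees of freedom in place of 7 and takes its spread from those groups alone, among which the K12 libraries with PA lay closest together.

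Without 1 library at a time, totals ranged from 277 (without replicate 1 of the dopaminergic strain) to 2588 for the dopaminergic strain against the control, from 2131 to 2657 for K12 with PA against the control, from 2198 to 5171 for the depleted diet and from 1169 to 3039 for PA on that diet. The lone library of a group was then assumed to vary like the other groups. For the dopaminergic strain against the control, camera adjusted p ranged over these settings from 6.6e-06 to 0.831 for the tricarboxylic acid cycle list and from 4.81e-09 to 0.821 for the respiratory chain list, both reversed without replicate 1 of the dopaminergic strain. For PA on the depleted diet the FMRFamide-like neuropeptide list ranged from 4.77e-09 to 0.274, reversed without replicate 2 of the depleted diet with PA. The cause was not tested.

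With the exon length trend removed per library, 16 named values reversed. They were ttn-1 at 0.095 in the pan-neuronal strain against the control, at −0.334 with PA on K12, at 0.049 with PA on the depleted diet and at 0.384 in the interaction, and unc-22 at 0.334 with PA on the depleted diet and 0.254 in the interaction. For PA against B12 they were mmab-1 (−0.732, adjusted p = 0.0153, range 0.0153 to 1 over the alternatives), mce-1 (−0.079), metr-1 (0.036), tomm-22 (−0.244), rpl-41.1 (−0.17), ptps-1 (−0.048), mca-3 (0.06), cup-14 (0.085), mrpl-36 (−0.014) and mrpl-54 (−0.01). The setting shifts genes by their length, and ttn-1 and unc-22 encode giant muscle proteins.

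Of the other values of named genes 21589 kept direction and side of the threshold, 902 lost the call and 192 gained it. Of list results 2361 kept call and direction, 400 lost the call (233 with an estimated correlation and 48 with fry) and 3 reversed. No list was tested with the exon length trend removed. Overlaps held in 38 of 40 alternatives. The other 2 moved in r with strand-specific counts, diet with B12 from −0.199 to −0.119 and PA on both diets from −0.102 to −0.0379. The cause was not tested.

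The replicate numbers were not taken as pairs. Residuals of equally numbered replicates correlated at r = −0.188 to 0.263 over 21 pairs of groups, with 4 above 0.1 and 4 below −0.1. A replicate block gave 7942, 2239, 6692, 10326, 3792, 4276, 2556, 10341, 9583 and 9072 calls in the order of the text. Most 2-fold changes were missed in simulated counts, where far fewer genes changed than were called here.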

Other observations

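The lists were fixed in advance, and of the tests here only the relation to exon length in groups other than the pan-neuronal strain on K12 was chosen after the result was seen. Spermatogenesis genes fell with PA on K12 in 33 of 34 (33 adjusted over the list alone) (adjusted p = 0.489 with an estimated correlation) and with B12 on the depleted diet in 31 of 34 (31 adjusted over the list alone) (adjusted p = 0.736 with an estimated correlation). Nuclear hormone receptor genes rose with PA on K12 in 116 of 197 (115 adjusted over the list alone) (adjusted p = 0.489 with an estimated correlation) and fell with B12 in 106 of 197 (106 adjusted over the list alone) (adjusted p = 0.771 with an estimated correlation). Genes of branched-chain amino acid breakdown fell in the pan-neuronal strain in 8 of 9 (8 adjusted over the list alone) against the control (adjusted p = 0.347 with an estimated correlation) and in 8 of 9 (8 adjusted over the list alone) against the dopaminergic strain (adjusted p = 0.259 with an estimated correlation). FMRFamide-like neuropeptide genes were higher with PA than with B12 in 23 of 30 (24 adjusted over the list alone) (adjusted p = 0.682 with an estimated correlation), as were intracellular pathogen response genes in 13 of 18 (14 adjusted over the list alone) (adjusted p = 0.644 with an estimated correlation). Nuclear-encoded genes of translation in mitochondria gave 23 higher and 4 lower of 65 tested (24 and 4 adjusted over the list alone) on the depleted diet (adjusted p = 0.865 with an estimated correlation).

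Across genes, the difference of a group from the mean of the others followed exon length at rho = −0.498 on the depleted diet with PA, −0.37 on the depleted diet alone and 0.171 with B12, against 0.151 on K12 with PA, 0.142 in the control strain, 0.117 in the dopaminergic strain and −0.052 in the pan-neuronal strain on K12.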
